A study of Mus musculus with 4 samples.

How the data were processed

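A single table was used, in which 14323 gene symbols each have 4 normalized columns, 1 per library. The deposited values were treated as a signal of unknown unit until tested. All 57292 values lie within 1e-06 reads of a whole multiple of a smallest step in their column, so whole reads were recovered by dividing by that step. The values equal reads divided by an effective library size under the TMM scaling of edgeR, with factors recomputed here as 1.00, 1.02, 1.01 and 0.966, up to a constant. The lowest summed count of a listed gene was 4 reads, so genes with fewer reads are not in the table. The ribosomal precursor Rn45s took 6.75%, 7.10%, 4.82% and 7.39% of reads, and none of the 13 genes of the mitochondrial genome list was in the table. No raw reads were used here.

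Per the labels' protocols, RNA was extracted from colony cells with TRI Reagent LS and purified on RNeasy columns. MGIEasy kits were used to deplete rRNA and build strand-specific libraries, starting at 200 ng. SCF was at 25 ng/ml and the other cytokines at 10 ng/ml each. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2, RSEM, edgeR and the mm10 build were used. The order and role of these tools, and the gene annotation, are not given in the sources used here. Gene coordinates, GC content, transcript length and shared sequence were taken from GENCODE release M21 on GRCm38, the same assembly as mm10, and 10637 tested genes (93.6%) had a GC value.

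The comparisons, the filter, the added constant, the gene lists, the naming rule and most alternative settings were fixed before the data were examined. Tested genes had a mean over the 4 libraries of at least 1 normalized count, and log2 values were taken after adding 0.5. The added constant shrinks log2 differences of low genes, so ratios are those of the normalized counts themselves. A gene counts as higher or lower at 2-fold or more in log2 values. The shared 4OHT effect was fitted with limma, without trend or robust options, on an additive model of cell type and treatment with 3 coefficients over 4 libraries. Adjusted p-values are Benjamini-Hochberg at a threshold of 0.05. The overlap of calls if independent is the product of both call counts over the number of genes.

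Gene lists numbered 32. They covered the targeted genes, the Hoxa and Hoxb clusters, MLL fusion targets, MLL and elongation complex genes, markers of stem cells and of each blood lineage, stromal cells and transcription factors. Further lists covered mitosis, DNA replication, CDK inhibitors, MYC and ribosome biogenesis, p53, interferon, NF-kB, cholesterol, glycolysis, lysosome, stress, housekeeping, mitochondrial and sex-linked genes. The median of a list was ranked among 10000 random lists matched in 20 bins of expression. A list was said to lie outside them below percentile 2.5 or above 97.5, which was judged for the 27 lists with at least 3 measured members. In ST-HSC cultures 7 lists lay above and 8 below, and in MPP2 cultures 5 and 9. Bootstrap intervals come from 10000 draws of list members, and do not cover variation between cultures.

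Genes were named by rule from genes with at least 10 normalized counts in the higher library. The rule took the 12 highest and 12 lowest log2 differences in either cell type. It added the 8 per direction with the largest weaker effect in both, the 6 per direction with the largest difference between cell types, and 2 to 4 members of each list by level and by change. Predicted, clone-named and small RNA genes were skipped. Counting intervals are exact conditional binomial 95% intervals on recovered reads. A gene at 0 reads was bounded at 3 reads in that library, worth 0.209 to 0.241 normalized counts. Both cover counting error alone, since no molecular barcodes are known and culture variation is not included. Shared sequence is the share of 31-base words of a gene's transcripts also found in another gene.

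Alternatives added after the data were seen were removal of the GC trend in 20 bins, use of genes with a GC value only, edgeR quasi-likelihood on recovered reads, and GC removal with a mean-variance trend. A self-test used simulated reads with 200 genes changed by the same fold in both cell types. Real differences were less alike in the 2 cell types (Pearson correlation 0.43), so the recovery in simulated reads may not carry over. In that self-test limma recovered 92% of 2-fold and 100% of 4-fold changes with 40 false calls. With trend it recovered 88% and 99% with 41 false calls, and edgeR 88% and 100% with 40, more false calls than the threshold allows, so calls of all tools near it are uncertain. Among unchanged simulated genes 20 passed 2-fold in ST-HSC, 23 in MPP2 and 0 in both, from simulated noise alone. Of 50 lists without a shift, 6 were placed outside random lists, so a single list just past the bound carries little weight. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.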

Results

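Gene expression was measured by RNA-seq in colonies grown from 2 kinds of mouse blood progenitor. Short-term haematopoietic stem cells (ST-HSCs) can rebuild all blood lineages for a limited time, and MPP2 cells are multipotent progenitors that lean toward platelet and red cell precursors. Per the labels, 100 cells of either kind were grown for 5 to 7 days in 1% methylcellulose with SCF, IL-6, IL-3 and GM-CSF, cytokines that favour myeloid colonies. The cultures held 4-hydroxytamoxifen (4OHT), the active form of tamoxifen, at 0.05 µM, or ethanol alone. The labels give the 4OHT cultures the conditional expression "MLL-ENL", a leukaemia fusion that joins the front part of MLL (gene Kmt2a) to ENL (gene Mllt1). The ethanol cultures are marked "control".

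Each of the 4 combinations of cell type and treatment had 1 library. Recovered depth was 14317891 reads for ST-HSC with ethanol, 13647704 for ST-HSC with 4OHT, 13705519 for MPP2 with ethanol and 12907412 for MPP2 with 4OHT. Levels are given as normalized counts, on a scale where 1 read was worth 0.0695 to 0.0802, and log2 differences were taken after adding 0.5 to them. Of the genes listed, 11368 (79.4%) passed the expression filter. A difference between a pair of libraries had no replicate check and carries no p-value. Only the effect shared by both cell types was tested.

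Kmt2a and Mllt1, the parent genes of the fusion, were at similar levels with and without 4OHT. Kmt2a stood at 80.3 normalized counts in ST-HSC cultures with ethanol and 72.1 with 4OHT, and at 91.1 and 84.2 in MPP2 cultures (log2 -0.16 and -0.11). Mllt1 stood at 60.1, 62.7, 50.9 and 59.0 in the same order (log2 0.06 and 0.21). The median of the pair was -0.05 and 0.05. A count per gene symbol cannot separate the fusion from its parents, so the labels for induction could not be checked from this table. The housekeeping list of 15 genes had a median log2 4OHT difference of -0.01 in ST-HSC and 0.07 in MPP2 cultures, inside the middle 95% of random lists matched on expression, with Actb at -0.01 and 0.19.

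In ST-HSC cultures, interferon-response genes stood far higher with 4OHT than with ethanol, led by Oasl2 and Usp18. The chemokines Ccl2 and Ccl7, which draw monocytes, were also higher, as were targets of p53 such as Phlda3 and markers of macrophages such as Mrc1 and Gpnmb. Thbs1 (thrombospondin 1), Tgm2 (a protein-crosslinking enzyme) and Nos2 (inducible nitric oxide synthase) were lower. The mast cell and cholesterol synthesis lists had medians below 0, with 6 of 13 and 0 of 20 members at least 2-fold lower. In all, 239 genes were at least 2-fold higher and 62 at least 2-fold lower, of which 45 and 8 passed 4-fold. The SD of log2 differences over genes was 0.38. These counts describe a single pair of cultures.

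The type I interferon response list had a median log2 difference of 2.92 (bootstrap 1.75 to 3.05), and all 19 measured members were above 0. At least 2-fold higher were 15 of them. Oasl2, an antiviral oligoadenylate synthetase-like gene at chromosome 5, 114896936 to 114912234 (GRCm38), went from 0.417 to 19.4 normalized counts, a ratio of 46.5 (95% counting interval 21.1 to 128). Usp18, which removes the ubiquitin-like protein ISG15 from its targets, had 0.904 and 16.5 (ratio 18.3, 10.5 to 34.9). Rsad2, the antiviral protein viperin, had 1.11 and 11.9 (ratio 10.7, 6.41 to 19.2), and Irf7, a transcription factor for interferon genes, had 3.69 and 31.3 (ratio 8.48, 6.37 to 11.5). Isg15 itself had a log2 difference of 3.05, and Oas1a 2.52. Mx1 had 1 read with ethanol and 59 with 4OHT (ratio 61.0, 10.5 to 2449). Rtp4, a chaperone induced by interferon, went from 0.487 to 10.5 (log2 3.48), with 12.5% of its 31-base sequences found in another gene. Ifi204, an interferon-inducible DNA sensor, had a log2 difference of 3.16 but shared 34.0% of its sequences, and Ifit3 shared 61.8% with Ifit3b, so the values of both are uncertain.

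Outside the interferon list, Ccl2 went from 7.86 to 79.99 normalized counts (ratio 10.2, 8.38 to 12.5) and Ccl7 from 0.626 to 13.9 (ratio 22.2, 11.4 to 49.2). The adenylate kinase gene Ak1 had a log2 difference of 2.77 (1.11 and 10.5), and Fam198b had 2.56. Cfb, complement factor B, had 2.73, with 75.5% of its sequences shared with an overlapping gene model. The p53 response list had a median of 0.59 (bootstrap 0.35 to 1.16), with 5 of 16 members at least 2-fold higher. Phlda3, a p53 target that restrains AKT, went from 1.11 to 13.5 (ratio 12.1, 7.28 to 21.7). Cdkn1a, which encodes the cell-cycle inhibitor p21, went from 90.0 to 205 (ratio 2.28, 2.13 to 2.44), and Ccng1, cyclin G1, from 141 to 262. Mdm2, which feeds back on p53, was close to level at log2 0.27.

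Monocyte and macrophage markers had a median log2 difference of 0.90 (bootstrap 0.65 to 1.31), and all 14 were above 0. The M-CSF receptor gene Csf1r had 67.0 normalized counts with ethanol and 129.6 with 4OHT, the mannose receptor gene Mrc1 30.04 and 83.3, and the scavenger receptor gene Cd36 0.765 and 6.90. Lysosome genes had a median of 0.38 (bootstrap 0.22 to 0.56), with Gpnmb, a glycoprotein of lysosome-rich macrophages, at 64.7 and 293 (ratio 4.53, 4.22 to 4.87). Dendritic and antigen-presenting genes had a median of 0.56 (bootstrap 0.43 to 0.62), among them the class II invariant chain Cd74 at 0.58 and H2-Aa at 0.56. Genes of MYC activity and ribosome biogenesis had a small upward median of 0.16 (bootstrap 0.05 to 0.25). The NF-kB list had 0.17 (bootstrap -0.10 to 0.74), with 3 of 17 at least 2-fold higher.

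Mast cell and basophil genes had the lowest median of all lists in ST-HSC cultures, -0.98 (bootstrap -1.27 to -0.28), with 6 of 13 at least 2-fold lower. Mcpt8, a basophil protease, went from 45.8 to 21.6 normalized counts and Prss34, a serine protease of mast cells and basophils, from 15.0 to 4.17 (log2 -1.73). Cholesterol synthesis genes were all below 0, 20 of 20, with a median of -0.52 (bootstrap -0.55 to -0.36). Hmgcs1, an early enzyme of that pathway, went from 309 to 183, and Nsdhl, a later enzyme, from 89.4 to 50.6. Scd1, which desaturates fatty acids, had 282 and 117, and Acss2, which makes acetyl-CoA from acetate, had 44.2 and 20.7. Neutrophil genes had a median of -0.34 (bootstrap -0.47 to -0.18), with 16 of 17 below 0. The antimicrobial granule genes Camp and Ltf had -0.90 and -0.37.

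Thbs1, at chromosome 2, 118111876 to 118127133, went from 1238 to 298 normalized counts. Its ratio was 0.241 (95% counting interval 0.233 to 0.249). Tgm2 went from 34.6 to 7.76 and Nos2 from 11.4 to 0.934 (ratio 0.0819, 0.0427 to 0.144). Fgd4, an activator of the GTPase CDC42, had a log2 difference of -1.27, and Bnip3, a mitophagy receptor that shares 20.3% of its sequences with other genes, had -1.41. Hist2h3c1 (-2.25), Gvin1 (-2.24), Eno1b (-1.54) and Selenbp1 (-1.18) were also among the largest drops, but 100%, 99.7%, 89.0% and 61.1% of their sequences occur in other genes, so these values are uncertain.

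Smaller downward medians in ST-HSC cultures were those of glycolysis (-0.21, bootstrap -0.24 to -0.08), MLL and elongation complex genes (-0.20), mitosis (-0.12) and DNA replication (-0.11). No member of the glycolysis or mitosis lists reached 2-fold. Mki67, a marker of cycling cells, had 593 normalized counts with ethanol and 317 with 4OHT, and the kinetochore genes Cenpf and Cenpe had log2 differences of -0.94 and -0.97. A stromal, endothelial and epithelial list with 4 measured members had a median of -0.44, which became 0.19 when low genes were not filtered. Inside the range of random lists lay MLL fusion targets outside Hox (0.05), stem and multipotent progenitor genes (0.19), granule proteins of early myeloid cells (-0.11), eosinophil (0.16), megakaryocyte (-0.13) and erythroid genes (0.01). The same held for the integrated stress (0.01), immediate early and heat shock (-0.10), transcription factor (0.01) and CDK inhibitor (-0.19) lists. The stem list lay near the bound, at percentile 96.4, with 4 of 13 members at least 2-fold higher and 0 lower. In the erythroid list the globin genes Hba-a2 and Hbb-b1 had 0 reads in both ST-HSC libraries, so no fall could be seen for them.

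Hox genes were scarce in all 4 libraries. In the Hoxa cluster list 6 genes were in the table and only Hoxa9 passed the filter, with 13, 49, 5 and 14 reads in ST-HSC ethanol, ST-HSC 4OHT, MPP2 ethanol and MPP2 4OHT. Its 4OHT to ethanol ratio was 3.90 (95% counting interval 2.08 to 7.83) in ST-HSC and 3.11 (1.06 to 11.0) in MPP2 cultures. In the Hoxb cluster list 2 were in the table and Hoxb4 alone passed, at 3.20, 3.23, 1.59 and 2.81 normalized counts. Meis1, a partner of HOX proteins, went from 1.46 to 3.95 in ST-HSC cultures and from 8.08 to 5.70 in MPP2 cultures. Pbx3 was near level in both, at log2 -0.06 and -0.22. Of the lymphoid list, 8 genes were in the table and 2 passed the filter. One of them, the IL-7 receptor gene Il7r, had 6.54, 15.6, 23.3 and 20.4.

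In MPP2 cultures, 4OHT went with lower globin and red cell genes, lower mast cell genes and lower Il6 (the cytokine interleukin 6) and Ptgs2 (cyclooxygenase 2). Higher were Mmp2 (a gelatinase that digests matrix), the p53 targets Phlda3 and Zmat3, the acute-phase gene Saa3 and interferon-response genes such as Rsad2 and Usp18. Here 150 genes were at least 2-fold higher and 193 at least 2-fold lower, of which 10 and 31 passed 4-fold, with an SD of 0.41. These counts too describe a single pair of cultures.

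Globin genes were read in numbers only in MPP2 cultures with ethanol. Hba-a2, an alpha globin gene, had 239 reads there and 0 with 4OHT, at least 71.7-fold lower, and Slc4a1, the red cell anion exchanger, had 195 and 0, at least 58.5-fold lower. Both had 0 reads in ST-HSC cultures. Hbb-b1, a beta globin gene, went from 571 to 16 reads (ratio 0.0312, 0.0177 to 0.0510) and Hba-a1 from 637 to 31 (ratio 0.0541, 0.0365 to 0.0776). Hba-a2 and Hba-a1 share 92.6% and 75.5% of their sequences with other genes, so the drop is that of alpha globin, not of either copy. The erythroid list had a median log2 difference of -1.46 (bootstrap -3.96 to -1.08) in MPP2 cultures, with 10 of 13 at least 2-fold lower. Gata1, the master regulator of red cell and platelet lineages, went from 21.1 to 9.71 normalized counts, and Klf1, an erythroid transcription factor, from 3.10 to 1.043.

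Mast cell and basophil genes had a median of -1.60 (bootstrap -2.04 to -1.26) in MPP2 cultures, with 11 of 13 at least 2-fold lower. Gzmb, a granzyme also made by cultured mast cells, went from 109 to 18.9 normalized counts (ratio 0.174, 0.151 to 0.200). Cpa3, mast cell carboxypeptidase, went from 293 to 70.9, Il1rl1, the IL-33 receptor, from 160.3 to 38.3, and the histamine-forming enzyme Hdc from 347 to 136. Gata2, a transcription factor of stem, mast and megakaryocyte cells, went from 206 to 71.2. The eosinophil list had a median of -0.62 with 3 of 7 at least 2-fold lower, among them Epx, eosinophil peroxidase, at log2 -1.16, and Prg2, at -1.03. Akr1c18, a steroid-reducing enzyme, went from 113 to 21.2. Megakaryocyte genes were near level at a median of -0.11, with the platelet chemokine gene Pf4 at -0.47 and the integrin gene Itga2b at -0.16. Within that list Rab27b, which handles platelet granules, stood at -1.67 and Vwf, von Willebrand factor, at 0.65.

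Il6 went from 56.9 to 7.22 normalized counts in MPP2 cultures, 7.88-fold lower (ratio 0.127, 0.101 to 0.158). Ptgs2 went from 25.1 to 3.45, Gem, a small GTPase, from 28.0 to 4.25, and Asb2, a ubiquitin ligase subunit, from 18.4 to 2.89. Tmtc2 (log2 -2.53) and the cadherin gene Cdh17 (-2.33) were among the largest drops. The NF-kB list had a median of -0.40 (bootstrap -1.17 to 0.25), and -0.15 once the GC trend described further on was removed. It was mixed, with 5 of 17 at least 2-fold lower, such as the chemokine gene Ccl3 at -1.18 and the inflammasome gene Nlrp3 at -1.20, and 1 at least 2-fold higher, Relb, an NF-kB subunit, at 1.05. Egr1, an immediate early transcription factor, went from 158 to 54.5.

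Mmp2, at chromosome 8, 92827291 to 92853420, went from 5.20 to 35.5 normalized counts in MPP2 cultures (ratio 6.83, 5.31 to 8.88). Phlda3 went from 2.45 to 12.9 (ratio 5.27, 3.62 to 7.86). Sulf2, which trims heparan sulphate, went from 4.91 to 18.3, Mfge8, which bridges dying cells to phagocytes, from 29.7 to 104, and Angptl2, an angiopoietin-like secreted protein, from 7.94 to 27.5. Nid2, a basement membrane protein, went from 1.88 to 10.1, and Hspa2, a heat shock protein, from 10.5 to 47.6.

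Interferon genes had a median of 1.13 (bootstrap 0.57 to 1.64) in MPP2 cultures, all 19 above 0 and 12 of them at least 2-fold higher. Rsad2 went from 4.11 to 17.0 normalized counts, Usp18 from 2.96 to 10.6 and Oasl2 from 2.81 to 7.30. Monocyte and macrophage genes had a median of 0.58 (bootstrap 0.24 to 1.02), with Csf1r at 54.2 and 128 and Mrc1 at 32.6 and 99.2. The chemokine receptor gene Ccr2, a marker of inflammatory monocytes, went the other way at -0.76. Dendritic and antigen-presenting genes had a median of 0.88 (bootstrap 0.55 to 1.11), with Cd74 at 49.5 and 118. Irf8, a transcription factor of monocytes and dendritic cells that belongs to the transcription factor list, stood at 7.65 and 15.3. The p53 list had 0.37 (bootstrap 0.08 to 0.56) and lysosome genes 0.36 (bootstrap 0.23 to 0.51), with Gpnmb at 243 and 731. Perp, a membrane protein counted among p53 targets, stood furthest below 0 at -1.55, among 4 of 16 members below 0.

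Smaller medians in MPP2 cultures were those of cholesterol synthesis (-0.29, bootstrap -0.37 to -0.12, 17 of 20 below 0), MLL fusion targets outside Hox (-0.31, or -0.20 with the GC trend removed), mitosis (-0.13) and glycolysis (-0.12). Msi2, an RNA-binding protein of stem cells, went from 42.8 to 22.5 normalized counts, and Psip1, a chromatin partner of MLL, from 46.1 to 25.4. Stem and multipotent progenitor genes had a median of -0.30, but 0.068 when only genes with a mean of at least 5 normalized counts were tested. Inside the range of random lists lay MLL and elongation complex (-0.13), neutrophil (0.08), stromal (-0.01), DNA replication (-0.02), MYC and ribosome biogenesis (-0.02), granule protein (0.15), integrated stress (-0.04), immediate early and heat shock (-0.07), transcription factor (0.12) and CDK inhibitor (-0.14) genes. Within the granule list Hp, haptoglobin, was past 2-fold, at 228 and 507.

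**Figure D1:**
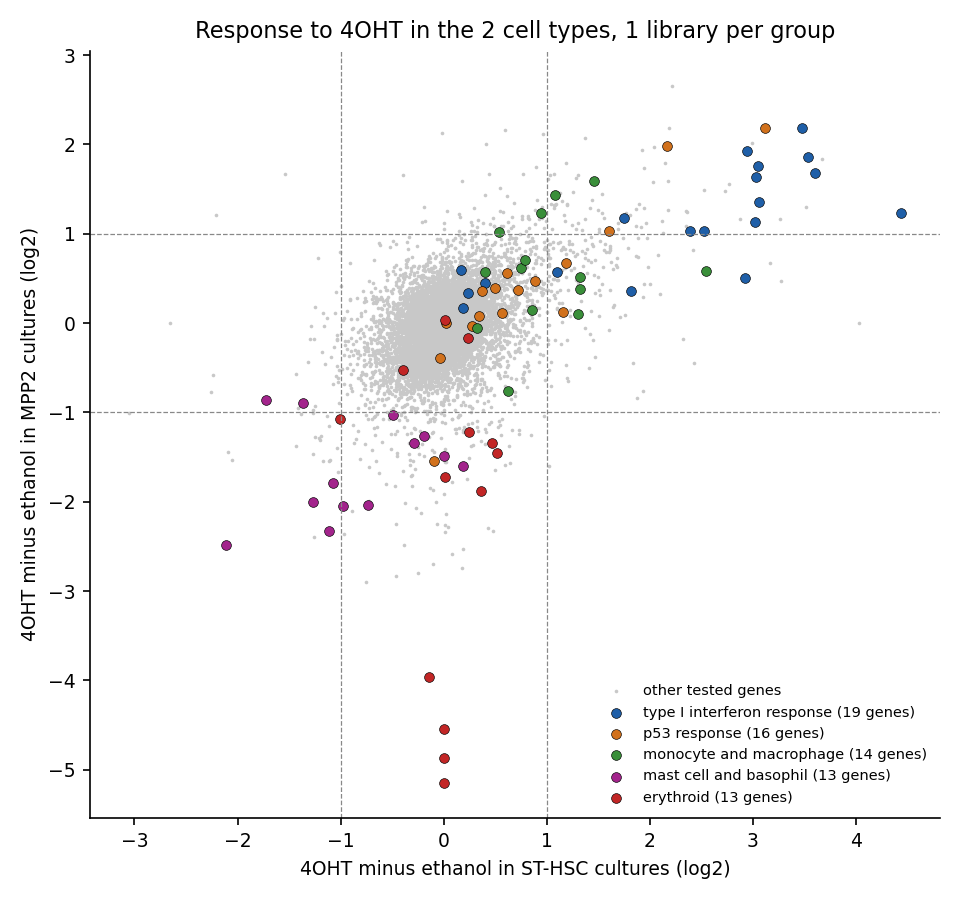
Log2 4OHT minus ethanol difference per gene in ST-HSC cultures (x axis) and MPP2 cultures (y axis) for 11368 genes, 1 library per group, with 5 gene lists coloured and dashed lines at 2-fold. At least 2-fold higher in both were 86 genes and at least 2-fold lower in both 24.

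**Figure D2:**
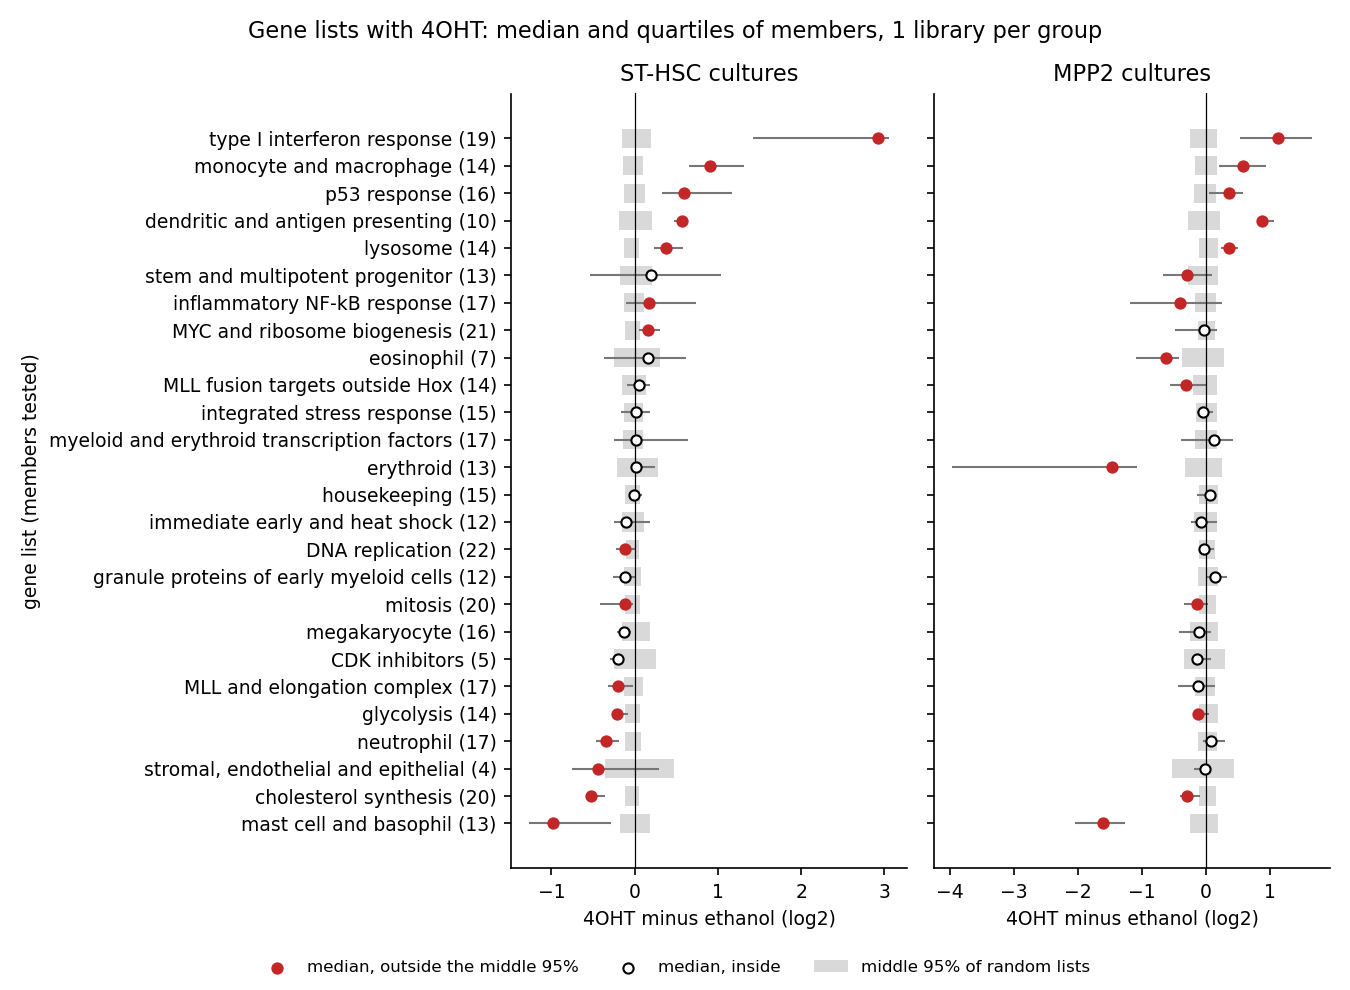
Median log2 4OHT minus ethanol difference of each gene list (points, with quartiles) in ST-HSC and MPP2 cultures, over grey bars for the middle 95% of 10000 random lists matched on expression. The interferon list had medians of 2.92 and 1.13 and the mast cell and basophil list -0.98 and -1.60.

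Genes that differed with 4OHT in both cell types included p53 targets, interferon-response genes, Mmp2 and macrophage genes on the upper side, and mast cell genes, Thbs1 and Tgm2 on the lower side. At least 2-fold higher in both were 86 genes, against 3.15 if the calls had been independent, and at least 2-fold lower in both were 24, against 1.05. Only 3 genes passed 2-fold in opposite directions. The log2 differences in the 2 cell types, which use different ethanol libraries, had a Pearson correlation of 0.43 and a Spearman correlation of 0.36 across genes. Genes are not independent replicates, so these correlations only describe the overlap.

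The shared effect was tested with limma in an additive model of cell type and treatment, where the other cell type is the only replicate and 1 residual degree of freedom is left. It called 5 genes higher and 1 lower, all at a limma adjusted p of 0.0478, while 1616 genes had an unadjusted p under 0.05. Under 6 other settings, among them the same column total and removal of the GC trend, it called 0. Zmat3, an RNA-binding p53 target at chromosome 3, 32334792 to 32366014, rose by log2 2.08 (standard error 0.13), from 10.5 to 49.0 normalized counts in ST-HSC and 13.0 to 52.7 in MPP2 cultures. Mmp2 rose by 2.44 (0.16) and Saa3, at chromosome 7, 46711998 to 46715700, by 1.93 (0.13). Gzmb, at chromosome 14, 56258838 to 56262260, fell by 2.30 (0.15). Qpct, which forms pyroglutamate at protein ends, rose by 2.18 (0.13) and AI607873, known by a clone name only, by 2.01 (0.13). Qpct and AI607873 fell outside the naming rule and were added once their values were seen.

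The limma count depended heavily on how variance was pooled. With a mean-variance trend limma called 337 genes higher and 259 lower, with 1946 genes at an unadjusted p under 0.05, and edgeR on the recovered reads called 333 and 270, with 1933. Residual SD fell from 0.18 in the lowest quartile of expression to 0.08 in the highest, which a single pooled variance does not follow. Of the 110 genes past 2-fold in the same direction in both cell types, 108 were called by edgeR and 6 by limma without a trend. The trend and edgeR calls shared 566 genes. The additive model also calls genes carried by 1 cell type, such as Hba-a2 and Slc4a1, at edgeR adjusted p of 2.9e-05 and 5.13e-05 with 0 reads in ST-HSC cultures.

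By edgeR, Phlda3 rose at an adjusted p of 6.29e-05, Mmp2 at 4.76e-06, Zmat3 and Saa3 at 1.98e-06, Sulf2 at 0.000112, Rtp4 at 0.000191, Rsad2 at 0.000157 and Ccl7 at 0.000583. These 8 were chosen on the upper side by the weaker of their 2 effects. On the lower side stood Gzmb (edgeR adjusted p 1.98e-06), Thbs1 (1.19e-05), Tgm2 (2.67e-05), Akr1c18 (2.02e-05) and Ms4a2, a chain of the high-affinity IgE receptor (0.000157). The other 3 were the cation transporter Slc22a3 (0.00309), the signalling adaptor Lat (0.00309) and the glutamate receptor gene Grm6 (0.00826). Ms4a2 went from 7.44 to 2.80 normalized counts in ST-HSC and from 41.0 to 9.87 in MPP2 cultures, and Lat from 2.29 to 0.719 and from 24.8 to 9.71. Mrc1 rose at 6.21e-06, Gpnmb at 6.21e-06, Csf1r at 0.000105, Cdkn1a at 0.00077 and Hoxa9 at 0.0289, the last with a limma adjusted p of 0.096.

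Within the lists, edgeR called 15 of 19 interferon genes higher over all genes and 18 when adjusted over the list alone, where limma called 0 and 16. For monocyte and macrophage genes edgeR called 10 of 14 (12 alone) and limma 0 (10 alone), and for antigen-presenting genes 6 of 10 (7 alone) and 0 (9 alone). For p53 genes edgeR called 6 higher and 1 lower (12 alone) and limma 1 higher (8 alone), and for lysosome genes 6 higher (10 alone) and 0 (6 alone). Mast cell and basophil genes had 11 of 13 lower by edgeR (13 alone) and 1 by limma (10 alone). Cholesterol synthesis had 7 of 20 lower by edgeR (15 alone) and 0 by limma (5 alone), with Hmgcs1 at an edgeR adjusted p of 0.00176, Nsdhl at 0.0022 and Idi1 at 0.00498. Mitosis had 4 lower by edgeR, Cenpf (0.00074), Cenpe (0.00128), Bub1 (0.00993) and Kif11 (0.0428), with 6 alone, and 0 by limma (2 alone).

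Erythroid genes had 7 lower by edgeR (8 alone), NF-kB genes 3 higher and 3 lower (8 alone), MLL fusion targets outside Hox 3 lower (4 alone), and stem genes 1 higher and 2 lower (4 alone). For these 4 lists limma called 0 over all genes and 1, 2, 0 and 2 over the list alone. The erythroid median was 0.01 in ST-HSC and -1.46 in MPP2 cultures, so a fall of the list was seen in MPP2 cultures only. In both ST-HSC libraries Hba-a2, Slc4a1 and Hbb-b1 had 0 reads, and Hba-a1 had 3 and 2. A fall of these genes could not have been seen there. The edgeR calls were made without removal of the GC trend described further on. That removal took limma with a mean-variance trend from 337 higher and 259 lower to 189 and 56. The stem call on the upper side was Ly6a, encoding the surface marker Sca-1, at an edgeR adjusted p of 0.0124, and those on the lower side included Angpt1, a niche growth factor, at 0.00705. MLL and elongation complex genes had 2 lower (4 alone), megakaryocyte genes 1 higher and 2 lower (5 alone), transcription factors 2 and 3 (5 alone), and eosinophil genes 1 lower (3 alone), where limma called 0 over all genes and 1, 2, 4 and 0 over the list alone. Glycolysis and housekeeping genes had 0 by both. Neutrophil genes had 1 higher and 0 lower by edgeR (1 alone) and 0 by limma (0 alone). Icam1, an adhesion molecule under NF-kB, rose at an edgeR adjusted p of 0.00041 and Relb at 0.0023.

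**Figure D3:**
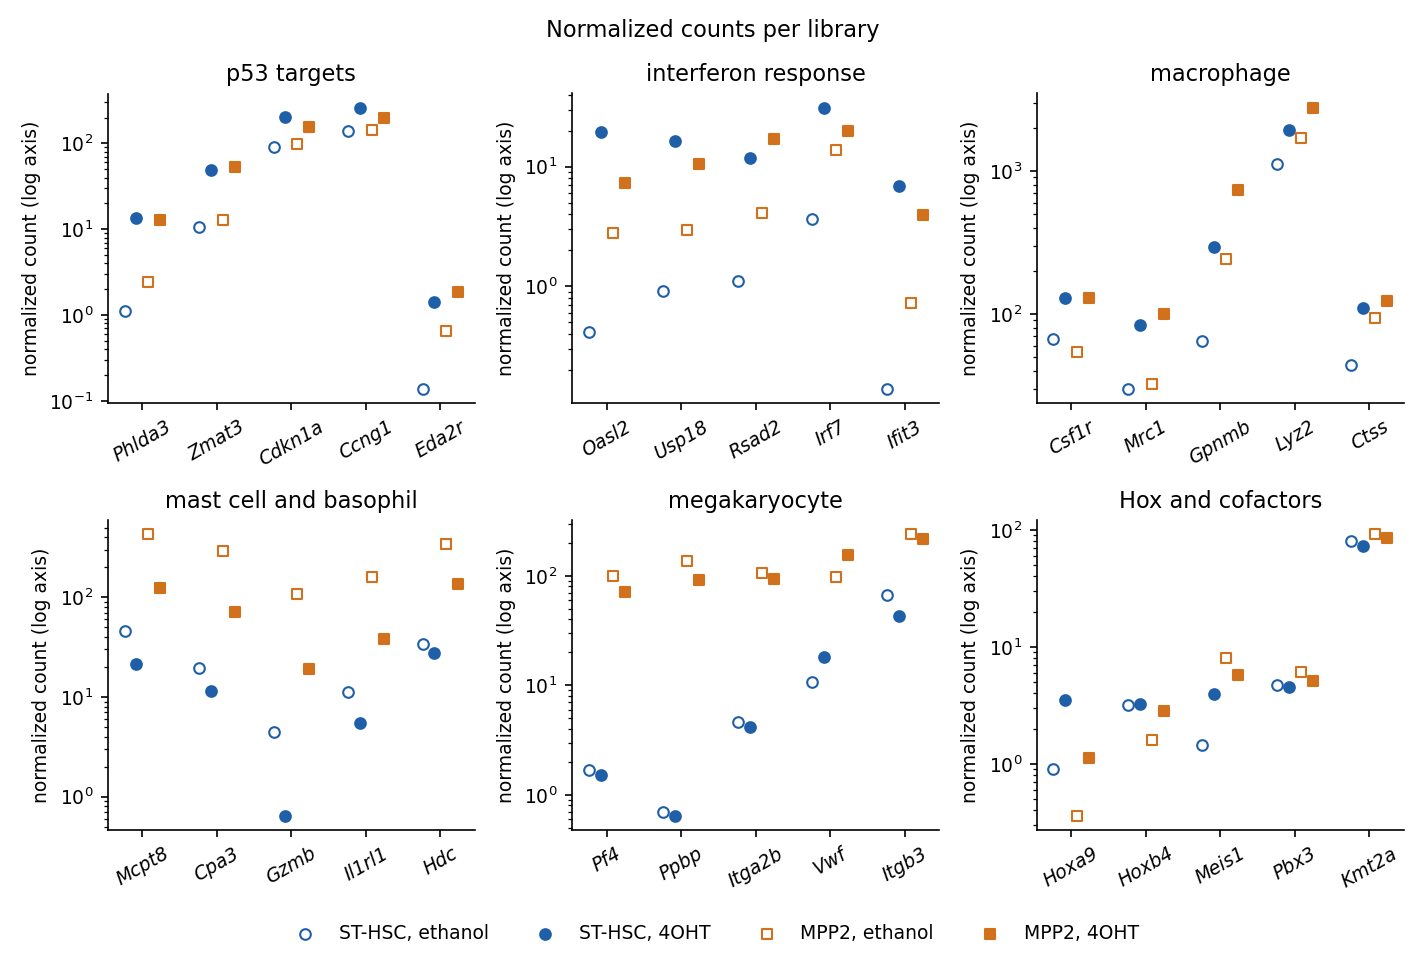
Normalized counts (log axis) in the 4 libraries, 1 per group, for 5 genes each of the p53, interferon, macrophage, mast cell and megakaryocyte groups and for Hoxa9, Hoxb4, Meis1, Pbx3 and Kmt2a. Gpnmb stood at 64.7 and 293 in ST-HSC cultures with ethanol and 4OHT and at 243 and 731 in MPP2 cultures.

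The size of the 4OHT difference was unlike in the 2 cell types for interferon genes such as Oasl2 and for a few single genes. The log2 difference in MPP2 exceeded that in ST-HSC cultures by at least 2 for 6 genes, and lay below it by at least 2 for 40. Hba-a2 (-5.15), Slc4a1 (-4.86), Hbb-b1 (-4.55) and Hba-a1 (-3.82) had the lowest values among genes named by rule, but with 0 to 3 reads in ST-HSC cultures no drop could have been seen there, so these values do not compare the response of the cell types. Oasl2 differed by -3.20, being higher with 4OHT in both but from 0.417 in ST-HSC and 2.81 in MPP2 cultures with ethanol. Cdh17 differed by -2.81. The 6 on the other side were Eno1b (3.21), Hspa2 (2.15), the villin-like gene Vill (2.05), Nos2 (2.04), Hist2h2aa2 (3.42) and Tmem254c (2.66). Hist2h2aa2 and Tmem254c lie below the level set for naming and were added once their values were seen. Short of a difference of 2, Gvin1 (1.66) and Nid2 (1.57) came next among the genes named by rule. Hspa2 was level in ST-HSC cultures, at 15.4 and 15.2 normalized counts, and Vill went from 13.6 to 10.2 there and from 6.35 to 21.1 in MPP2 cultures. With 1 library per group no test of these differences exists.

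Log2 4OHT differences also moved with the GC content of transcripts. Spearman correlation with GC was 0.18 in ST-HSC and 0.48 in MPP2 cultures over 10637 genes. In MPP2 cultures the median was -0.27 for transcripts under 45.2% GC and 0.17 for those over 56.1%. In ST-HSC cultures it was -0.09 and 0.03. With this trend removed, 216 of the 239 genes higher and 52 of the 62 lower in ST-HSC cultures stayed past 2-fold, and in MPP2 cultures 110 of 150 and 144 of 193. Some were lost because they have no GC value, 21 in ST-HSC and 29 in MPP2 cultures. The interferon medians were then 2.91 and 1.10.

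**Figure D4:**
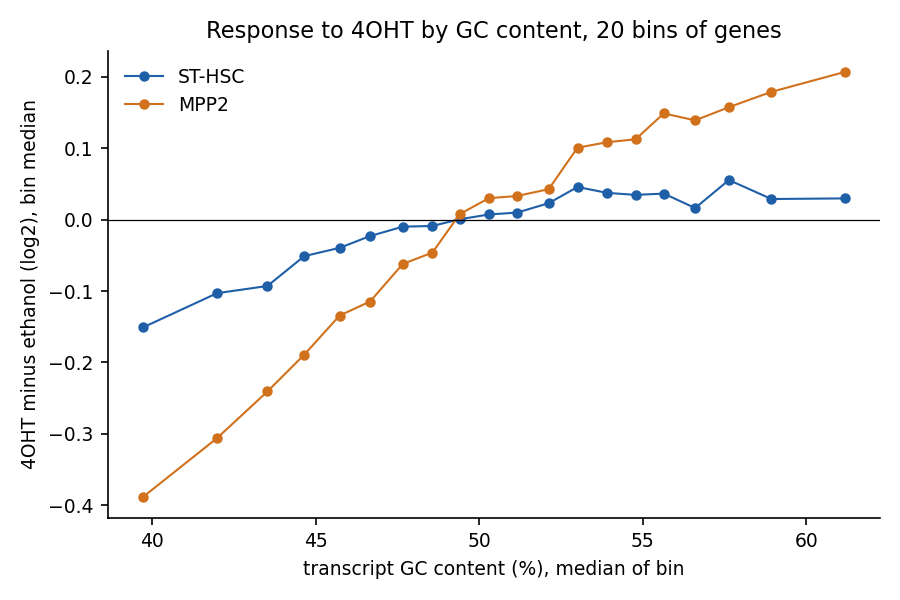
Median log2 4OHT minus ethanol difference (y axis) in 20 bins of transcript GC content in percent (x axis) for ST-HSC and MPP2 cultures, 1 library per group. In MPP2 cultures transcripts under 45.2% GC had a median of -0.27 and those over 56.1% had 0.17.

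Without 4OHT, colonies from MPP2 cells held far more mast cell, megakaryocyte, red cell and eosinophil transcripts than those from ST-HSCs. Colonies from ST-HSCs held more of the granule proteins of early myeloid cells, such as Mpo (myeloperoxidase), and of antigen-presenting genes. In ethanol 713 genes were at least 2-fold higher in MPP2 and 98 lower, with 247 and 9 past 4-fold and an SD of 0.66. The libraries also differed in sex-linked genes. Xist, the transcript of the inactive X, had 0 and 5 reads in ST-HSC and 12086 and 7437 in MPP2 libraries. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty together had 1760 and 1472 in ST-HSC and 0 in both MPP2 libraries. The list of these 5 genes had a median log2 4OHT difference of -0.09 in ST-HSC cultures, and in MPP2 cultures Xist, the only member with reads, stood at -0.55. Cell type and sex of the source animals therefore cannot be told apart here.

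Mast cell and basophil genes had a median log2 difference of 3.49 between MPP2 and ST-HSC cultures in ethanol, with 13 of 13 at least 2-fold higher. Cpa3 stood at 19.5 and 293 normalized counts and Gzmb at 4.45 and 109. Megakaryocyte genes had 2.81, with 14 of 16 at least 2-fold higher. Ppbp, a platelet chemokine, stood at 0.695 and 138 and Itga2b at 4.66 and 105. The median was 3.06 for erythroid genes and 2.90 for eosinophil genes, with Epx at 10.6 and 94.9. Genes of the NF-kB response (1.12), stem cells (1.01), neutrophils (0.90), macrophages (0.72) and interferon (0.67) lay on the same side, with smaller medians for lysosome (0.40), p53 (0.37) and transcription factor genes (0.23). Antigen-presenting genes had -1.22, granule proteins -0.88, MYC and ribosome biogenesis genes -0.56 with all 21 below 0, and DNA replication genes -0.35. Mpo had a log2 difference of -1.21 and Elane, neutrophil elastase, -1.08.

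With 4OHT, 613 genes were at least 2-fold higher in MPP2 than in ST-HSC cultures and 194 lower, with an SD of 0.62. Higher in both settings were 399 genes, against 38.4 if the calls had been independent, and lower in both 39, against 1.67. The correlation across genes was 0.78. Megakaryocyte genes had a median of 2.88, close to that in ethanol, with Ppbp at 0.647 and 90.7 normalized counts. Mast cell genes had 2.49, eosinophil genes 2.02, neutrophil genes 1.13 and erythroid genes 1.03. Interferon genes lay on the other side from ethanol, at -0.62, with Irf7 at 31.3 in ST-HSC and 19.8 in MPP2 cultures. MYC and ribosome biogenesis genes had -0.81 and antigen-presenting genes -0.75. Npm1, a nucleolar protein of ribosome assembly, stood at 750.3 and 344. Of the 811 genes past 2-fold in ethanol, 27 lie on X or Y, and of the 807 in 4OHT, 31 do. Among all 11368 tested genes, 332 lie on X.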

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

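The rule for opposite directions was fixed before the data were examined. All tests of explanations given here were chosen after the pattern had been seen, and only for the GC-corrected medians was the outcome still unknown when the prediction was written. Grouped by GC content, median log2 4OHT differences ran only from -0.27 to 0.17 in MPP2 and from -0.09 to 0.04 in ST-HSC cultures. Removal of a trend of that size could hardly change the large list medians judged here, so that outcome too was largely set in advance.

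Eno1b, Hist2h2aa2 and Rps4l passed 2-fold in opposite directions in the 2 cell types. Eno1b, a copy of the glycolytic enolase gene, went from 129 to 43.9 normalized counts in ST-HSC cultures and from 118 to 374 in MPP2 cultures, a difference of log2 3.21. Of its sequence 89.0% is shared, mostly with Eno1, so a shifting split of reads between the copies is a candidate explanation. The sum of Eno1 and Eno1b was 2244 and 2068 in ST-HSC and 1998 and 2131 in MPP2 cultures. Eno1b is only a small part of that sum, so the sum cannot test this explanation. The histone gene Hist2h2aa2 had 26 reads and then 0 in ST-HSC cultures, at least 8.39-fold lower, and 9 and then 27 in MPP2 cultures (ratio 3.34, 95% counting interval 1.52 to 8.06), a difference of 3.42. All of its sequence (100%) occurs in another gene model. Rps4l, a pseudogene of a ribosomal protein by annotation with 25.96% shared sequence, went from 3.69 to 7.98 and from 3.68 to 0.882, a difference of -2.61. Hist2h2aa2 and Rps4l fell outside the naming rule. For each of the 3 genes the difference was not tested.

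The interferon list was higher with 4OHT in both cell types. Counting noise is an unlikely source, since the counting interval of the ratio lay above 1 for 17 of 19 members in ST-HSC and 18 of 19 in MPP2 cultures. The GC trend is unlikely too, because medians with the trend removed were 2.91 and 1.10. A larger share of macrophages cannot be ruled out, as the interferon median exceeded the macrophage median by 2.02 (bootstrap 0.63 to 2.30) in ST-HSC and 0.55 (-0.07 to 1.09) in MPP2 cultures, but macrophage genes started from a higher level in ethanol (45.8 against 1.11 and 68.2 against 4.11). With 0 libraries given 4OHT without MLL-ENL, an effect of the drug or of the induction itself may equally be the source.

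The ST-HSC and MPP2 libraries differed in sex-linked genes. A swap of 1 library between cell types is unlikely, as 0 cell types held libraries of different sex-linked state. Of the 811 genes past 2-fold in ethanol, 27 lay on X or Y and 758 were autosomal, so the difference was not confined to sex chromosome genes. With 332 tested genes on X and 6 listed on Y, a majority of the 811 was not possible there. The count therefore does not weigh an effect of sex. Sex or animal might still contribute to autosomal differences between the cell types, because 0 treatments held both cell types in the same sex-linked state. Comparisons of 4OHT with ethanol were made within a cell type and so within the same sex-linked state.

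Mast cell and basophil genes were lower with 4OHT in both cell types. In MPP2 cultures the mast cell median lay below the megakaryocyte median by log2 -1.49 (bootstrap -2.02 to -1.02), with 16 of 16 megakaryocyte genes well read. This argues against a dilution that lowers every other cell type alike. Erythroid (-1.46) and eosinophil (-0.62) medians were lower too, while the neutrophil median (0.08) was not. The megakaryocyte list was chosen once its median was known, so dilution of some cell types only is not ruled out. In ST-HSC cultures the gap was -0.85 (-1.16 to -0.12), but only 7 of 16 megakaryocyte genes were well read and no conclusion was drawn. The GC trend is an unlikely source in MPP2 cultures, where the median with the trend removed was -1.61. The counting interval lay below 1 for 13 of 13 members in MPP2 and 10 of 13 in ST-HSC cultures, which a smaller share of mast cells and a lower output per cell would both predict.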

How the results depend on the processing

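The settings with GC removal, with genes holding a GC value only and with edgeR were chosen after the result had been seen, and all others were fixed beforehand. Differences between settings are described, and the cause was not tested except where fewer genes were tested or a threshold was stricter.

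With a constant of 0.1 added, ST-HSC genes lower with 4OHT numbered 108 and genes lower in MPP2 than ST-HSC in ethanol 149. The difference between cell types passed its threshold for 11 genes above and 82 below, and the correlation was 0.41. With a constant of 2 added, counts were 139 higher and 15 lower in ST-HSC, 76 and 109 in MPP2, and 41 and 4 in both. MPP2 against ST-HSC then had 49 lower in ethanol and 387 higher and 89 lower in 4OHT, and the difference had 2 above and 14 below.

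Without a filter the difference had 10 above, and the correlation was 0.36. With a mean of at least 5 normalized counts, fewer genes were tested and counts were 125 and 30 in ST-HSC, 83 and 79 in MPP2, 400 and 61 between cell types in ethanol, 370 and 113 in 4OHT, and 48 and 14 in both. The difference had 17 below and the correlation was 0.47. At 4-fold, a stricter threshold, counts were 45 and 8 in ST-HSC, 10 and 31 in MPP2, 247 and 9 between cell types in ethanol, 131 and 10 in 4OHT, and 5 and 1 in both. With a difference threshold of 3 there were 2 above and 6 below.

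The limma count of 5 higher and 1 lower was the least stable result. It was 0 and 0 with a constant of 0.1 added (1515 genes at an unadjusted p under 0.05), without a filter (1755), with the same column total (1498), with the median ratio (1557), with the GC trend removed (1279) and with genes holding a GC value only (1507). It was 180 and 48 with a constant of 2 added, 162 and 68 with at least 5 normalized counts, 124 and 32 at an adjusted p under 0.1, and 5 and 1 with robust eBayes. With a mean-variance trend it was 337 and 259, with GC removal as well 189 and 56, and with edgeR 333 and 270. Of the 245 calls with trend and GC removal, 236 were also among those with trend alone. Mast cell, p53 and interferon genes rest on the values in both cell types and not on this count, and the cause of its spread was not tested.

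An alternative list median counted as the same if it lay inside the bootstrap interval over members, which is wide for some lists. For a named gene the counting interval was used. Reversed means a change of sign, judged only for lists outside random lists and genes past 2-fold. Whether a list still lay outside random lists was not checked again. Of 378 alternative list medians 370 were the same, 6 moved and 2 were reversed. The reversed ones were the stem list in MPP2 cultures with at least 5 normalized counts (0.068) and the stromal list in ST-HSC cultures without a filter (0.19). Of 702 alternatives for named genes 653 were the same, 49 moved and 0 were reversed. Leaving out single libraries was not possible, since the additive model on 3 libraries has no residual degrees of freedom. The additive model compared treatments within each cell type, and no replicates could be matched beyond that, because each group holds 1 library and the labels carry no replicate numbers.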

Other observations

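The families described here, and the tests of their possible sources, were chosen after their values had been seen.

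Guanylate-binding proteins, interferon-induced GTPases that attack pathogen vacuoles, were higher with 4OHT in ST-HSC cultures, and less clearly so in MPP2 cultures. Their median log2 difference was 1.68 over 5 genes in ST-HSC cultures, with 4 at least 2-fold higher. In MPP2 cultures it was 0.76, with 2 at least 2-fold higher. Gbp2 went from 1.60 to 5.61 normalized counts in ST-HSC and from 1.59 to 4.41 in MPP2 cultures, and Gbp5 from 0.417 to 3.38 and from 0.361 to 0.963. In MPP2 cultures Gbp3 (8 and 16 reads) and Gbp5 (5 and 12 reads) had counting intervals of the ratio that include 1, at 0.898 to 6.00 and 0.875 to 9.67. Gbp7 had log2 differences of 0.35 in ST-HSC and -0.36 in MPP2 cultures. The Ms4a family of membrane proteins had a median of 1.64 over 7 genes in ST-HSC cultures and 0.21 in MPP2 cultures, the latter inside the range of random lists. Ms4a6c, Ms4a6d and Ms4a7, found on monocytes and macrophages, stood at 1.61, 1.94 and 2.13 in ST-HSC and 0.84, 1.29 and 1.01 in MPP2 cultures. Ms4a4c and Ms4a6b were higher in ST-HSC cultures at 1.64 and 1.71, but had too few reads in MPP2 cultures to place, 9 and 10 for Ms4a4c (ratio 1.24, 0.451 to 3.44) and 6 and 6 for Ms4a6b (ratio 1.11, 0.297 to 4.16). Ms4a2, the mast cell member, was lower in both, at ratios of 0.377 and 0.241. Ms4a3, a marker of granulocyte and monocyte progenitors, was level at 0.05 and 0.21.

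Chemokine genes had a median of 0.65 over 13 genes in ST-HSC and 0.23 in MPP2 cultures. In ST-HSC cultures Ccl9 went from 97.3 to 201 normalized counts, Ccl4 from 30.7 to 62.9, Cxcl10 from 3.89 to 14.3 and Cxcl16 from 1.11 to 4.53. Of these, Ccl9 (312 and 230) and Ccl4 (98.3 and 68.3) were lower with 4OHT in MPP2 cultures. Cxcl16 had 1.73 and 2.89 there (ratio 1.67, 0.968 to 2.92). In MPP2 cultures 3 chemokine genes were at least 2-fold higher, Ccl2 (31.03 and 70.3), Ccl7 (2.53 and 10.3) and Cxcl10 (5.05 and 12.03). At least 2-fold lower were Cxcl2, which draws neutrophils (48.4 and 21.2), and Ccl3 (471 and 208). The stefin A family, protease inhibitors of neutrophils, had -0.73 over 4 genes in ST-HSC cultures, where Stfa1, Stfa2, Stfa2l1 and Stfa3 stood at -0.34, -0.76, -0.70 and -0.99. In MPP2 cultures the median was -0.33, with 0.07, -0.46, -0.19 and -0.51 in the same order, but 0.35, -0.18, 0.20 and -0.22 once the GC trend was removed. By edgeR, Stfa2 and Stfa3 fell over both cell types at adjusted p of 0.00863 and 0.00386.

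A growing share of macrophages might carry part of the higher interferon genes. The interferon median exceeded the macrophage median by 2.02 (0.63 to 2.30) in ST-HSC and 0.55 (-0.07 to 1.09) in MPP2 cultures, and the higher starting level of macrophage genes leaves the question open in both. Sorting of macrophages from such colonies before RNA extraction would separate these readings.

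The p53 targets Phlda3, Zmat3 and Cdkn1a were higher together with lower Cenpf and Cenpe, which may reflect a slowed cell cycle. However, no mitosis gene reached 2-fold in either cell type. The mitosis medians with the GC trend removed were only -0.11 in ST-HSC and -0.09 in MPP2 cultures. The 65 replication histone genes tested had medians in opposite directions, -0.14 in ST-HSC and 0.22 in MPP2 cultures, without GC removal. These values do not point to a shared slowing. DNA content was not analysed here. Whether these genes follow the fusion or the drug remains open, with 0 libraries given 4OHT without MLL-ENL, and cultures of wild-type cells with 4OHT would answer it.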
